A study of Homo sapiens with 6 samples.

How the data were processed

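Total RNA of HEK293T/17 cells, without its short RNAs, was used, per the labels' protocols. It was broken into fragments, treated with CMC or mock-treated, repaired at the ends and ligated to a 3′ adapter. It was then reverse transcribed in 1 of 3 ways, and the cDNA was size-selected, circularised, amplified with barcodes and sequenced in a single lane. Neither an alkaline step after CMC nor molecular identifiers are described in the labels. Trimmomatic 0.32 and Bowtie 1.0 are named in the submitters' processing notes, while their settings, the mismatches allowed, the reference sequence's origin and the counting program are not given in the sources used here.

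For each of the 6 libraries the authors deposited a table for 18S rRNA (1869 positions) and one for 28S rRNA (5070 positions), 12 tables in all. Per the file headers, each row holds the position, the reference base, the counts of reads crossing it in all and with A, C, G and T, and the count of reads stopping there. The authors also deposited a mismatch rate and a stop frequency, each a fraction between 0 and 1. These were recomputed from the counts. The mismatch rate equals the reads with another base over the crossing reads, and the stop frequency equals the stops over stops plus crossing reads, within 1e-09 at every position of all 12 tables. Reads with no base made up at most 0.00200% of crossing reads. No other normalization is applied to these values. Positions are those of the deposited rRNA sequences, counted from 1, and no genome build applies. Human rDNA occurs in many near-identical copies, so a position can hold more than 1 base in the cells, and reads from copies are not separated.

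How stops were placed was checked on the tables. The crossing count rises from the second to the third position by exactly the stop count at the first in 12 of 12 tables, and at no position does the count rise by more than the stops allow. A stop is therefore booked at the template base not copied, the outermost base of each read is left out of the crossing counts, and these relations hold in all 3 conditions. They cover stop placement only. The HIV RT tables are named differently from the SuperScript III tables, with a word that hints at a step at the read edges, and whether trimming or alignment differed between them is not given. Of the offsets 1 nt 5′, none and 1 nt 3′, none gave the highest mean stop share at 3 modified control positions of the mock libraries, 31.9% against 10.5% and 8.04%. This rests mostly on position 1322 of 28S, since another offset was higher at 4530 of 28S in all 3 mock libraries and at 1248 of 18S in both SuperScript III mock libraries. The last stop lies 18 nt from the 3′ end in every table, so no shorter read running to the 3′ end was counted. If the same limit holds for all reads, stops that leave a shorter cDNA are missing.

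The list of modified positions was written from general knowledge before the data were examined. It had 99 well established pseudouridines, 13 doubtful ones, 5 controls and 7 other modifications. A pseudouridine was used only where the reference base is U, which left 98 and 8. Mutation share is mismatched over crossing reads and stop share is stops over stops plus crossing reads, both in percent. A position entered a comparison with at least 100 crossing reads in both libraries, which removed between 4 and 27 of the 6939 positions. There is 1 library per group, so no p-value across samples or across sites is given. List medians have bootstrap intervals from 10000 draws over sites. A list's median is also placed among 10000 random lists of unlisted U matched on coverage in 5 bins, as a description of these libraries. Each position was compared between the CMC and mock library with a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over all tested positions of both rRNAs, and called at an adjusted value under 0.05 with a difference of at least 5 points. Such a call compares 2 libraries, not 2 treatments. Neighbouring bases were compared by the range of the 4 group medians against 10000 shuffles. Shares of single libraries have 95% Wilson intervals.

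The sites named were chosen by a rule set before the data were examined. For each condition and measure it takes the 6 called listed pseudouridines with the largest change, the 3 called positions outside the lists with the largest change, and the listed sites with the largest and smallest ratio of mutation to stop change among those called for either. It also takes all controls and other modifications, and the listed sites called in every condition, or the 6 with the largest mean change. A site whose mutation or stop share did not rise has no ratio.

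The calls were tested on simulated data with the depths and mock shares of the HIV RT mutation and SuperScript III magnesium stop comparisons (6935 and 6912 positions). Of 50 positions each raised by 6 or 10 points, 100% were called in both. Of those raised by 4 points, 0 and 1 were called, and none of the 6735 and 6712 positions not raised by 2 to 10 points was called. The latter include 98 U raised by 1 point for a simulated list. The simulation covers counting error only and holds no variation between libraries. At these depths the minimum difference required for a call largely fixes such outcomes. They therefore give no rate of false calls for the real libraries. A simulated list of 98 U raised by 1 point lay at percentile 100 in both comparisons, and lists left as they were lay at percentiles 36.2 and 54.0. The background U of these simulations did not change with CMC. The real unlisted U rose by medians of 0.854 and 3.49 points in these comparisons. The simulated percentiles therefore do not show how small a rise the list comparison can detect in the real libraries.

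Alternatives set before the data were examined were minimums of 30 and 1000 reads, the doubtful sites added, each rRNA alone, pooled reads, log2 ratios with 1 read added, neighbouring stop offsets, bars of 2 and 10 points, a bar at the 99th percentile of unlisted positions, 50 nt left out at each end, the CMC library alone, called sites alone, sites with no other within 3 nt, and means over sites. Added after seeing the data were unlisted U more than 3 nt from any listed pseudouridine as the background, the neighbouring bases of unlisted U, and unweighted means of the change over sites. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.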

Results

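The series measured how reverse transcription reads pseudouridine (Ψ), an isomer of uridine, in the ribosomal RNA of HEK293T/17 cells, a human embryonic kidney line. RNA fragments were treated with CMC, a carbodiimide that adds a bulky group to U, G and Ψ and is held longest by Ψ, or were mock-treated. Each was copied under 3 conditions. HIV reverse transcriptase (HIV RT) was used with magnesium, and SuperScript III, an engineered murine leukaemia virus enzyme, was used with manganese or with magnesium. This gave 6 libraries, 1 per combination, so no difference between treatments or conditions has a replicate check. At every position of 18S and 28S rRNA the deposited tables hold the reads that crossed it, their bases and the reads that stopped there. The mutation share is the percent of crossing reads with another base, and the stop share is the percent of stops among stops plus crossing reads. Reads that ended right after copying a position are in neither of its counts. Differences are given in percentage points (points), CMC minus mock.

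The HIV RT libraries held 21206954 ended reads with CMC and 47002169 without. The SuperScript III libraries held 24611914 (CMC) and 32327311 (mock) with manganese, and 23849776 and 23209210 with magnesium. Median coverage per position ranged from 60611 reads (HIV RT with CMC, 28S) to 282421 reads (HIV RT mock, 18S). Among the listed pseudouridines the fewest crossing reads in any library were 7069. The widest 95% Wilson interval there was ±0.663 points for mutation and ±0.877 points for stop. These intervals cover at most the counting error of independent reads. PCR reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for that.

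Of 99 pseudouridines listed as well established, 98 fell on a U of the deposited reference sequence, against 16.6% U over all positions. The other 1 was left out. The remaining 1047 unlisted U served as the background.

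The first comparison asked how CMC changes mutation at known pseudouridines. With HIV RT the median mutation share over the 98 sites was 4.67% with CMC and 0.460% without, and the median site difference was 4.05 points (95% bootstrap interval over sites 3.02 to 5.13). With SuperScript III and manganese the medians were 4.08% and 0.112%, a difference of 3.98 points (3.05 to 4.83). With SuperScript III and magnesium they were 0.544% and 0.0545%, a difference of only 0.484 points (0.381 to 0.591). The share was higher with CMC at 98, 98 and 97 of the 98 sites. At unlisted U the median differences were 0.854, 0.704 and 0.125 points. Each list median lay above all 10000 random lists of unlisted U matched on coverage, whose highest medians were 1.33, 1.03 and 0.201 points. An unweighted mean over sites, added after the data were seen, gave 6.43, 5.57 and 1.26 points, and pooling reads over sites gave 6.48, 6.38 and 1.46 points. Without CMC, the median mutation share at the listed sites was not above that at unlisted U, which was 0.617%, 0.154% and 0.0595%.

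The median change in stops was larger than that in mutations in every condition. The median stop share at the 98 sites was 18.5% with CMC and 2.21% without for HIV RT, and the median site difference was 14.5 points (11.3 to 20.4). For SuperScript III with manganese the shares were 9.87% and 2.35%, with a difference of 7.74 points (5.58 to 10.5). For SuperScript III with magnesium they were 20.1% and 1.91%, with a difference of 18.3 points (14.7 to 22.4). Unlisted U had median differences of 2.89, 1.17 and 3.49 points. All 3 list medians again lay above all 10000 random lists, whose highest medians were 5.21, 3.60 and 6.50 points. The stop share was higher with CMC at 98, 95 and 97 sites. An unweighted mean over sites gave 18.0, 13.4 and 21.5 points and pooled reads gave 20.5, 17.3 and 26.6 points.

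**Figure D1:**
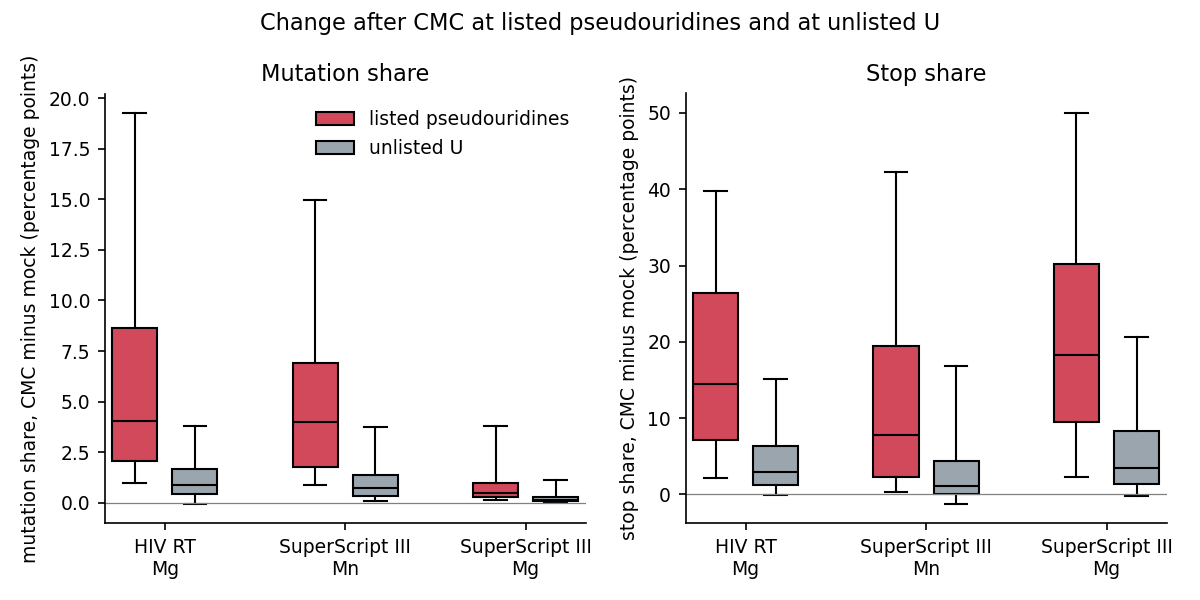
Change in mutation share (left) and stop share (right) after CMC, in percentage points, for listed pseudouridines (red) and unlisted U (grey) in each reverse transcription condition. Boxes show quartiles and medians and whiskers the 5th to 95th percentiles over positions; the listed medians are 4.05, 3.98 and 0.484 points for mutation and 14.5, 7.74 and 18.3 points for stop.

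Single positions were then tested between the CMC and mock library of each condition with a two-sided Fisher's exact test. A position was called when the Benjamini-Hochberg adjusted value passed 0.05 and the share differed by at least 5 points. At these depths the test alone passes very small differences, so the size bar decides most calls, and each call compares 2 libraries rather than 2 treatments. For mutation, HIV RT had 73 positions that rose and 7 that fell; 67 of the 73 were U, 41 were listed pseudouridines and 23 were unlisted U. SuperScript III with manganese had 89 that rose and 23 that fell, with 68 at U, 37 at listed pseudouridines and 29 at unlisted U. SuperScript III with magnesium had 11 that rose and 6 that fell, with 6 at U, 3 at listed pseudouridines and 3 at unlisted U. By rate, 41.8%, 37.8% and 3.06% of listed sites were called, against 2.20%, 2.78% and 0.287% of unlisted U. With a bar of 2 points the counts that rose were 295, 373 and 48, and with 10 points they were 26, 17 and 7.

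For stops, 698 positions rose with HIV RT, 580 with SuperScript III and manganese and 637 with SuperScript III and magnesium, while 254, 137 and 127 fell. U made up 435, 303 and 505 of the positions that rose, or 62.3%, 52.2% and 79.3%, and the rest were A, C or G. Listed pseudouridines accounted for 82, 62 and 90 of the positions that rose, which is 83.7%, 63.3% and 91.8% of the list. Unlisted U accounted for 346, 236 and 411, or 33.1%, 22.6% and 39.4% of those tested. A bar of 2 points gave 1501, 1129 and 1237 positions and a bar of 10 points gave 284, 258 and 323. Requiring the change to exceed the 99th percentile of unlisted positions with the same base left 101, 86 and 103, of which 30, 15 and 30 were listed. That bar is set on the unlisted positions themselves, so nearly the same number of them passes in every condition by construction. The totals are therefore largely fixed by the bar, while the listed counts are not.

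Across conditions, 57 listed pseudouridines were called for stop in all 3 and 3 were called for mutation in all 3. HIV RT and SuperScript III with manganese shared 25 mutation calls, while 16 were called with HIV RT but not manganese and 12 with manganese but not HIV RT. Of the 98 sites, 94 were called for stop or mutation in at least 1 condition. The 4 without a call, named here because they are so few and after their values were seen, were Ψ1232 of 18S and Ψ4403, Ψ4420 and Ψ4493 of 28S.

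The 3 sites with a mutation call in every condition were Ψ406 of 18S and Ψ4471 and Ψ4521 of 28S. Ψ4471, at the centre of AUCAUUGUGAAGCAG (positions 4464 to 4478 of 28S), had mutation shares of 30.4%, 39.1% and 16.7% after CMC with HIV RT, manganese and magnesium, against 0.624%, 0.342% and 0.108% in the mock libraries. Ψ4521, at the centre of GGGAACGUGAGCUGG (4514 to 4528), had 22.7%, 11.1% and 16.8%, and Ψ406, at the centre of CCACGGGUGACGGGG (399 to 413 of 18S), had 19.3%, 14.8% and 14.6%. The stop change at Ψ4521 was 2.12, 1.34 and 1.38 points and was not called in any condition. It gave the largest ratio of mutation to stop change with magnesium, 12.2.

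With HIV RT the largest mutation changes were at Ψ1692 of 18S (33.9 points), Ψ4471 (29.8), Ψ1347 of 18S (28.3), Ψ1744 of 28S (28.1), Ψ4521 (22.2) and Ψ3715 of 28S (19.3). With manganese they were at Ψ4471 (38.8), Ψ1643 of 18S (28.2), Ψ3734 of 28S (22.2), Ψ1692 (19.2), Ψ34 of 18S (18.6) and Ψ1347 (15.0). The conditions differed at some of these sites. Ψ1744 had a mutation share of 29.1% with HIV RT after CMC but 3.85% with manganese, and Ψ3715 had 19.6% and 2.65%. Ψ1643 went the other way, with 10.2% and 28.6%. With magnesium the same 3 sites had 0.338%, 0.301% and 1.10%.

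Stops were largest at sites in other contexts. Ψ1445 of 18S, at the centre of AACUUCUUAGAGGGA (1438 to 1452), had stop shares of 60.9%, 56.8% and 65.4% after CMC and 4.71%, 3.71% and 5.11% without. Ψ4361 of 28S rose by 52.2, 42.6 and 67.6 points, Ψ1367 of 18S by 36.3, 63.9 and 65.9 points, Ψ572 by 38.6, 47.7 and 50.4 points, Ψ822 by 31.4, 52.7 and 52.2 points and Ψ649 by 39.8, 42.2 and 38.4 points. These were the 6 sites with the largest mean stop change among those called in every condition. With HIV RT the leading sites also included Ψ3844 (46.8 points), Ψ3639 (44.7) and Ψ3851 (41.0) of 28S. With manganese these 3 had 10.6, 12.7 and 10.4 points. With magnesium Ψ815 of 18S rose by 49.99 points.

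The balance of mutation and stop spanned a wide range. The largest ratio of mutation to stop change was 38.4 with HIV RT, at Ψ93 of 18S, where mutation rose by 15.6 points and the stop share changed by 0.406 points. With manganese it was 78.7, at Ψ1625 of 18S, where mutation rose by 11.3 points and the stop difference was 0.143 points, so the ratio rests on a small divisor. The smallest ratios were 0.00924 at Ψ815 with HIV RT, 0.0194 at Ψ649 with manganese and 0.00313 at Ψ5010 of 28S with magnesium. Across the 98 sites Spearman's rho between mutation and stop change was -0.226 with HIV RT, -0.292 with manganese and -0.105 with magnesium, and Pearson's r was -0.285, -0.250 and -0.158. Without the 2 sites farthest from the median stop change, r was -0.286, -0.258 and -0.165. These correlations run across sites within a pair of libraries, and sites are not independent replicates.

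**Figure D2:**
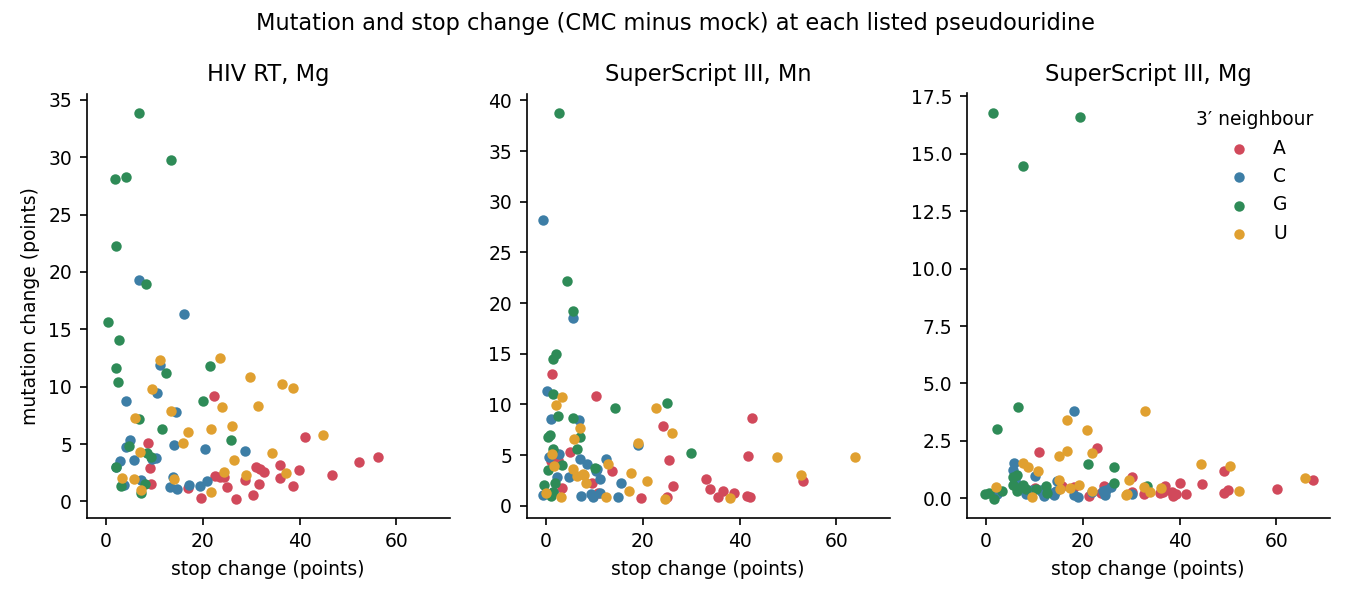
Change in mutation share (vertical) against change in stop share (horizontal), CMC minus mock, in percentage points, with 1 point per listed pseudouridine coloured by its 3′ neighbouring base; the vertical scales differ between conditions. The highest mutation changes with HIV RT lie mostly at sites followed by G and many of the highest stop changes at sites followed by A; rho is -0.226, -0.292 and -0.105.

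The conditions were then compared site by site. HIV RT gave a mutation change 3.37 points (median paired difference, interval 2.45 to 4.25) above SuperScript III with magnesium and was higher at 94 of 98 sites. Manganese gave 2.99 points (2.07 to 3.87) more than magnesium with the same enzyme and was higher at 97 sites. HIV RT and manganese were not told apart, with a difference of 0.634 points (-0.124 to 1.48), higher with HIV RT at 57 sites. In the CMC libraries alone that difference was 1.08 points, with an interval above 0. For stops, magnesium exceeded manganese at 86 of 98 sites (manganese minus magnesium, median -6.33 points, -8.12 to -4.49). HIV RT lay between, 3.62 points (1.71 to 5.34) above manganese and below magnesium (-2.47 points, -4.32 to -1.01). With pooled reads the HIV RT and manganese stop difference was 3.23 points, with an interval that included 0, and HIV RT minus magnesium was -6.07 points. The pooled mutation difference was 0.105 points between HIV RT and manganese and 4.91 points between manganese and magnesium. The names of the HIV RT tables differ from the others and hint at a step at the read edges, so a difference in processing cannot be ruled out in comparisons of the 2 enzymes. The ranking of sites was shared more for stops, with rho of 0.821 between manganese and magnesium, 0.790 between HIV RT and magnesium and 0.629 between HIV RT and manganese, than for mutation, with rho of 0.642, 0.386 and 0.486. Differences in ranking were described and not tested.

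The title of the series concerns sequence context, and the base 3′ of the pseudouridine, which is copied just before it, separated the sites. A stop at the site leaves a cDNA that ends opposite this base. Whether cDNAs with different end bases were recovered alike was not tested, so stop differences by 3′ base cannot be credited to reverse transcription alone. With a 3′ A (25 sites) the median stop change was 30.4 points with HIV RT, 24.9 with manganese and 36.6 with magnesium. With a 3′ G (23 sites) it was 6.85, 2.44 and 6.71 points. A 3′ U (26 sites) gave 22.6, 10.3 and 21.4 points and a 3′ C (24 sites) gave 10.8, 7.07 and 13.9 points. None of 10000 shuffles of the base among sites gave a range of medians as large in any condition. Mutation ran the other way. A 3′ G had median changes of 10.4 points with HIV RT and 6.78 with manganese, while a 3′ A had 2.21 and 2.43. The range of medians exceeded all 10000 shuffles with HIV RT and 99.7% of them with manganese. With magnesium the highest median was at a 3′ U, 0.785 points, the range exceeded 96.5% of shuffles, and it exceeded 90.5% among the 70 sites with no other listed pseudouridine within 3 nt.

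The 5′ neighbour separated the listed sites less. For mutation with HIV RT a 5′ G (21 sites) had a median change of 8.30 points and a 5′ C (21 sites) 2.34 points, a range above 99.6% of shuffles. For manganese and magnesium mutation the ranges exceeded 59.8% and 15.4% of shuffles, and for stops 33.0%, 3.12% and 45.7% in the order HIV RT, manganese, magnesium. Among the 70 sites with no other listed pseudouridine within 3 nt the percentiles were 96.7, 54.5 and 62.4 for mutation and 91.1, 52.1 and 64.1 for stops. Unlisted U, grouped in the same way after the data were seen, had stop changes of 8.61, 7.54 and 10.9 points before an A and 1.53, 0.193 and 1.93 points before a C. Their mutation change before a G was 1.58 points with HIV RT and 0.972 with manganese, against 0.439 and 0.436 before an A. The 5′ base also separated unlisted U, with mutation ranges above 99.3%, 99.97% and 99.99% of shuffles and stop ranges above 99.4%, 99.98% and 81.3%. These ranges were small, 0.290, 0.354 and 0.0727 points for mutation and 1.22, 1.37 and 0.935 points for stop. The 3′ ranges were 1.14, 0.537 and 0.0428 points for mutation and 7.08, 7.34 and 8.99 points for stop, so with magnesium the 5′ range of mutation was the wider.

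**Figure D3:**
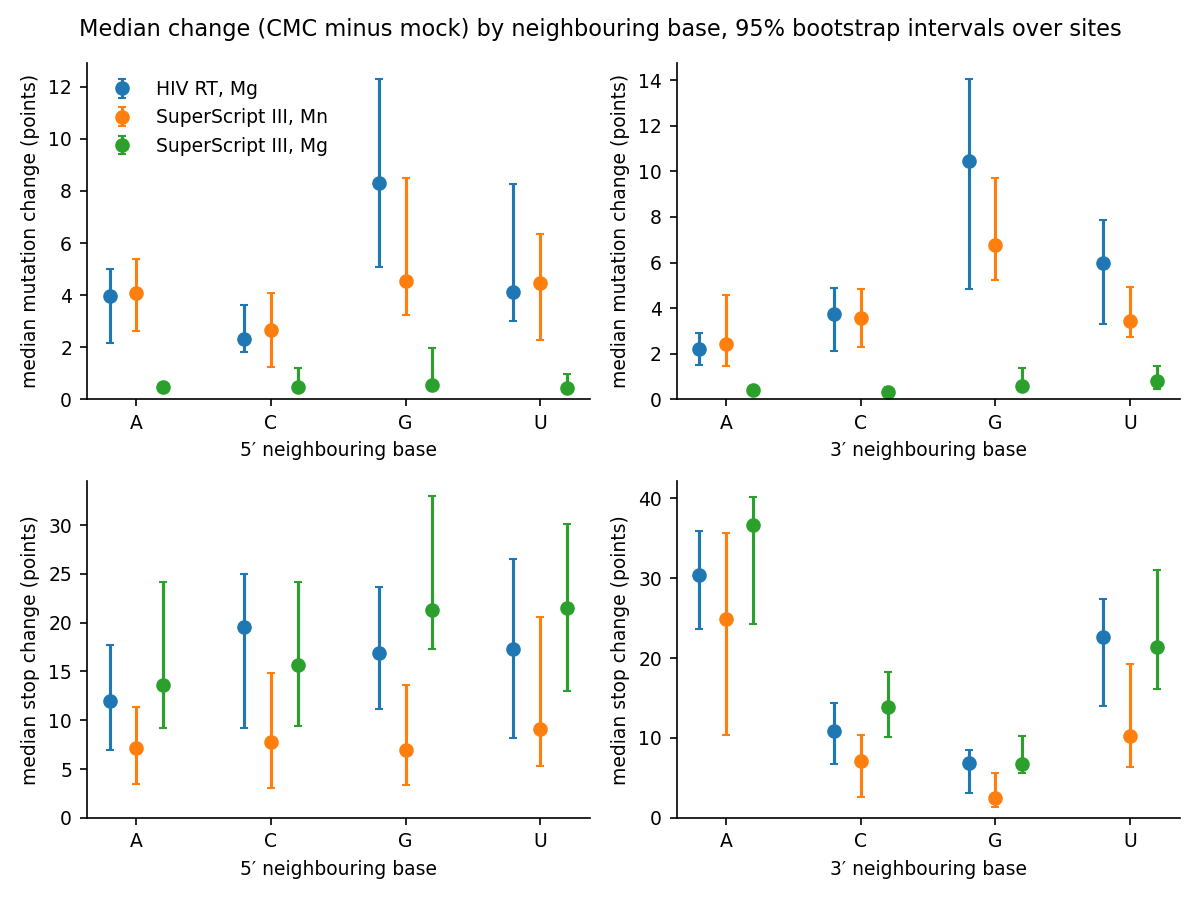
Median change in mutation (top) and stop share (bottom), CMC minus mock, in percentage points, for listed pseudouridines grouped by the 5′ (left) and 3′ (right) neighbouring base. Points are medians and bars 95% bootstrap intervals over the 21 to 30 sites of each group; stop medians run from 6.85 points before G to 30.4 before A with HIV RT.

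The mismatched bases at listed sites were mostly C, which corresponds to reading the U as C. Over the 98 sites 78.9% of mismatched reads were C after CMC with HIV RT, 70.3% with manganese and 77.5% with magnesium. A made up 13.7%, 21.1% and 16.4%, and G 7.37%, 8.64% and 6.11%. In the mock libraries C made up 44.3%, 47.6% and 51.4% and A 33.7%, 35.7% and 30.2%. Wilson intervals were at most a fraction of a point wide around most of these shares (for C after CMC with HIV RT, 78.8% to 79.0%), but intervals that resample sites were far wider, 72.3% to 83.8% for that share and 55.4% to 81.0% with manganese. As a mean over sites the C share after CMC was 67.6%, 61.7% and 62.2%. Without CMC this mean was 45.0%, 55.4% and 53.7%, so the shift toward C was smaller per site than in pooled reads. C was the most frequent mismatch at 84, 73 and 77 of the 98 sites with CMC and at 68, 79 and 82 without, so with either SuperScript III condition it led at fewer sites after CMC.

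Background errors differed between conditions and bases. In the mock libraries the median mutation share of unlisted positions was 0.769% at A, 0.676% at C, 0.609% at G and 0.617% at U with HIV RT. With manganese it was 0.458%, 0.413%, 0.426% and 0.154%, and with magnesium 0.0887%, 0.0989%, 0.0824% and 0.0595%. After CMC the median at unlisted U was 1.56%, 0.949% and 0.208%, and at G 0.877%, 0.844% and 0.146%. At A it was 0.587%, 0.599% and 0.112% and at C 0.530%, 0.553% and 0.180%.

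**Figure D4:**
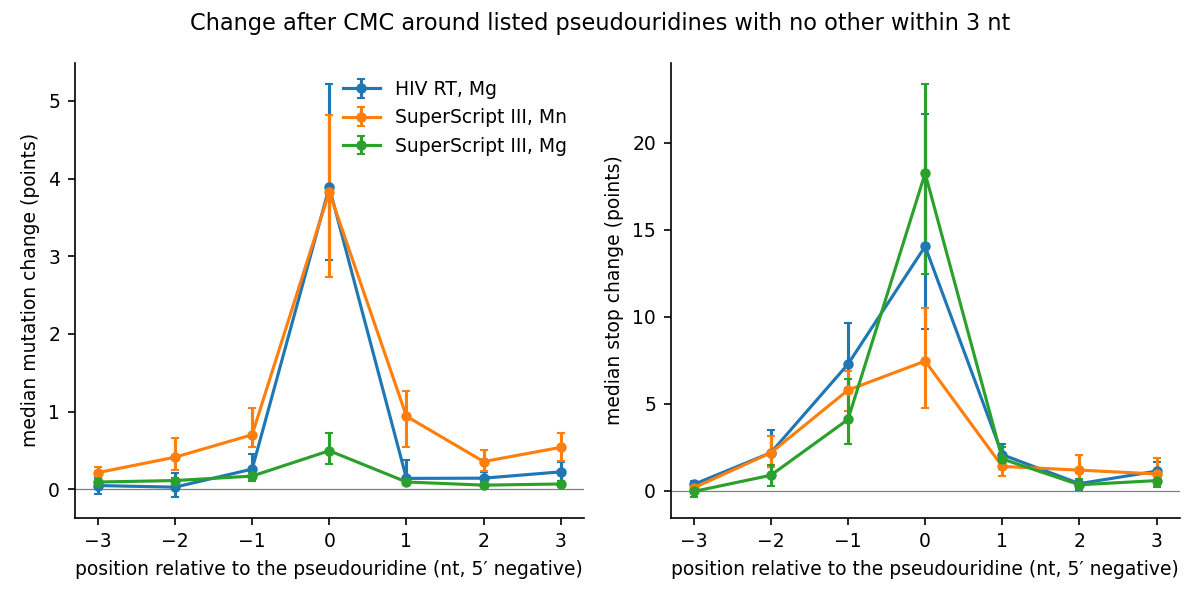
Median change in mutation share (left) and stop share (right) after CMC, in percentage points, from 3 nt 5′ to 3 nt 3′ of the 70 listed pseudouridines with no other within 3 nt. Bars are 95% bootstrap intervals over sites; the highest median lies at the site in every condition, and the stop change 1 nt 5′ of it is 7.29 points with HIV RT, 5.79 with manganese and 4.11 with magnesium.

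Positions with modifications that block or alter base pairing served as controls without CMC. The 1-methyladenosine at position 1322 of 28S, in CGUCUUGAAACACGG (1315 to 1329), had mock stop shares of 78.0% with HIV RT, 77.5% with manganese and 87.2% with magnesium. After CMC these fell to 65.0%, 63.2% and 79.9%. Its mutation shares were 53.1%, 34.1% and 19.0% without CMC and 53.2%, 32.0% and 14.3% with it. The 3-methyluridine at 4530 of 28S had mutation shares of 40.5%, 27.4% and 32.4% without CMC and 29.4%, 28.9% and 31.7% with it, and mock stop shares of 1.10%, 2.15% and 2.03%. Its stop share rose with CMC to 6.91% with HIV RT and 17.7% with manganese and was 4.99% with magnesium. The position lies 2 nt 5′ of the listed Ψ4532, and 2 nt 5′ of the 70 listed sites with no other within 3 nt the median stop change was 2.20, 2.19 and 0.899 points. The hypermodified U at position 1248 of 18S (1-methyl-3-aminocarboxypropyl pseudouridine), in AUUUGACUCAACACG (1241 to 1255), had mock mutation shares of 81.1%, 59.7% and 67.0%, which fell to 54.5%, 50.4% and 59.6% after CMC. Its stop share rose from 10.5% to 51.1% with HIV RT and from 26.8% to 68.1% with magnesium, and was 1.85% and 3.68% with manganese. Among the dimethyladenosines near the 3′ end of 18S, position 1850 had mock stop shares of 46.0%, 41.9% and 94.98%. Position 1851 had at most 0.332%, where a stop leaves a read of 18 nt to the 3′ end of 18S, the shortest such read in any table.

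The other listed modifications had mock mutation shares of 3.19% or less. The mock mutation share of N4-acetylcytidine was 1.11%, 1.69% and 0.592% at 1337 and 3.19%, 1.25% and 0.542% at 1842 of 18S. The 7-methylguanosine at 1639 of 18S had 2.95%, 1.35% and 0.520%, with mock stop shares of 12.3%, 15.1% and 15.5%. The 5-methylcytidines of 28S had 0.698%, 1.76% and 0.252% at 3782 and 1.38%, 0.990% and 0.171% at 4447. The N6-methyladenosines had 0.275%, 0.156% and 0.0331% at 1832 of 18S and 0.688%, 0.107% and 0.0475% at 4220 of 28S. No mutation or stop share at these 7 sites was called as higher after CMC. Stop shares fell by over 5 points at 1639 with manganese (-7.74) and magnesium (-6.84) and at 4220 with HIV RT (-7.30).

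**Figure D5:**
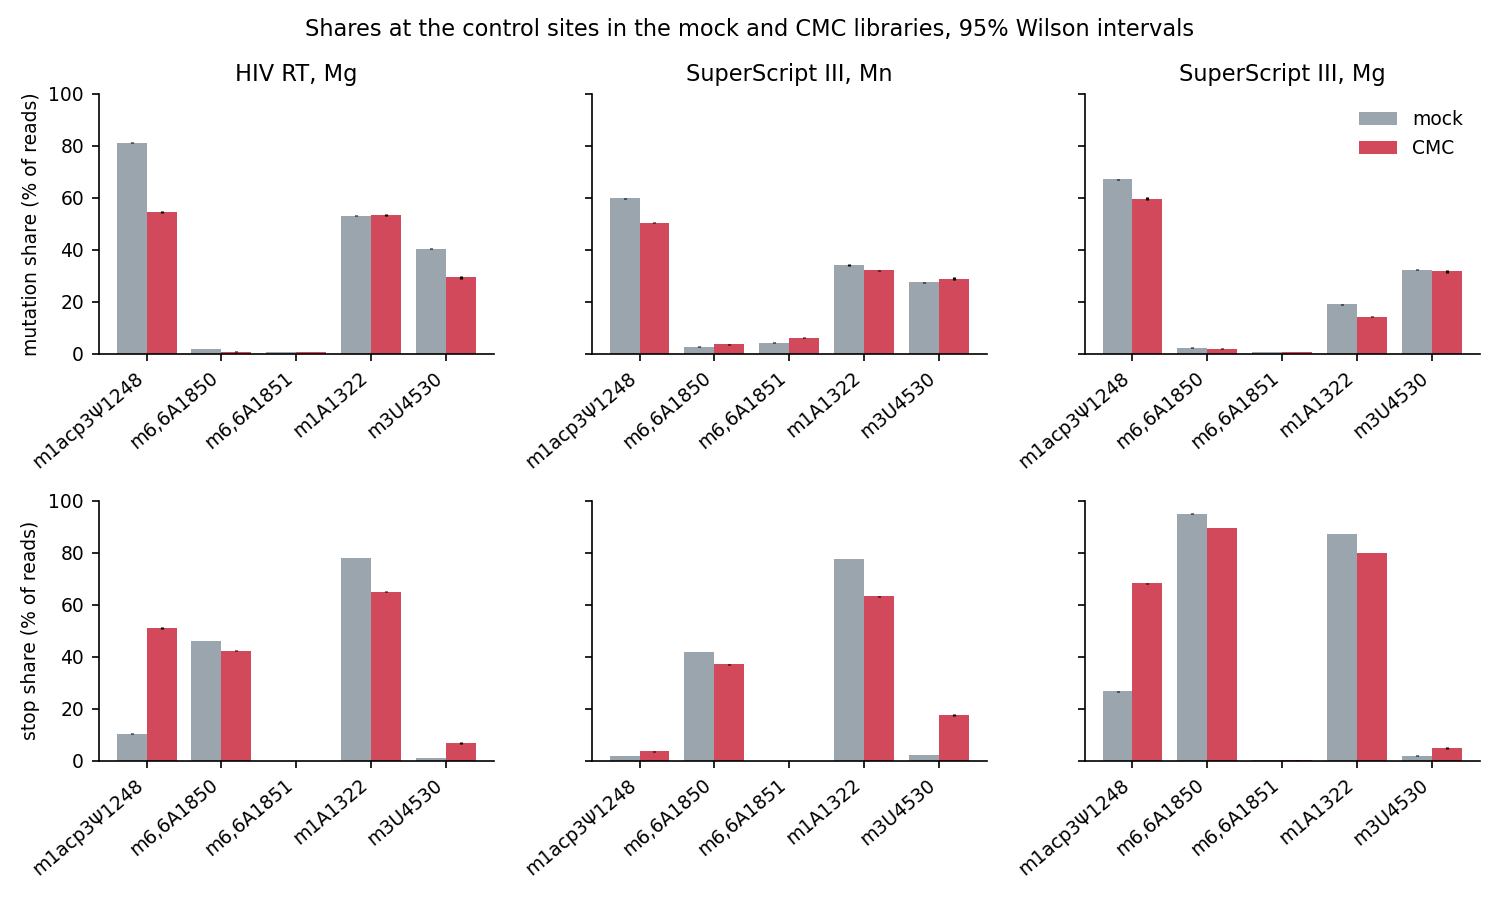
Mutation share (top) and stop share (bottom), in percent of reads, at the 5 control positions in the mock (grey) and CMC (red) libraries of each condition, with 95% Wilson intervals that are narrower than the lines at most bars. The stop share at position 1248 rises from 10.5% to 51.1% with HIV RT, and position 1851 has a mock stop share of at most 0.332%.

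Outside the lists, the largest mutation changes with HIV RT were at U 1642 of 18S (16.9 points), U 3457 of 28S (13.5) and U 597 of 28S (11.5). With manganese they were at U 965 of 18S (17.6 points), U 3482 of 28S (11.6) and A 2 of 18S (11.1), and with magnesium at A 3343 (12.4), G 4150 (11.1) and U 3482 (10.3) of 28S. Several already had raised mock shares in the same condition. These were 27.8% at U 597, 13.0% at G 4150, 9.37% at A 2, 8.78% at U 3457 and 4.13% at A 3343. At U 1642, U 965 and U 3482 the mock shares were 1.14% or less. Some of these rest on few reads or lie at an end. U 3457 had 490 crossing reads with CMC and 706 without in the HIV RT libraries and leaves under the minimum of 1000 reads, and A 2 leaves when 50 nt are left out at each end. U 1642 and U 965 each lie 1 nt from a listed pseudouridine. The largest stop changes with HIV RT were at U 1861 (40.5 points), U 1792 (39.6) and U 4360 (35.2) of 28S. With manganese they were at U 1791 (48.5), A 4298 (47.1) and U 3441 (42.1), and with magnesium at U 827 (51.4), A 4298 (46.2) and U 1792 (45.0). U 1861, A 4298 and U 4360 lie 1 nt from a listed pseudouridine, whereas U 1792, at the centre of CAAACUUUAAAUGGG (1785 to 1799), lies 10 nt from the nearest. U 3441 had 262 and 123 crossing reads with manganese and U 827 had 1174 and 555 with magnesium, so both leave under the minimum of 1000 reads.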

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

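At 2 listed pseudouridines of 18S the stop share moved in opposite directions after CMC in different conditions, with each change past Fisher's exact test between its 2 libraries. At any size of change, 6095 of 6935 positions passed that test for stop with HIV RT. With manganese 5849 of 6924 passed and with magnesium 5835 of 6912, so passing it says little about the direction of a small change. The difference between conditions was not tested, since each rests on single libraries. At Ψ1643, in GAGGAAUUCCCAGUA (1636 to 1650), the stop change was 10.5 points with HIV RT, 10.2 points with SuperScript III and magnesium and -0.600 points with SuperScript III and manganese, the condition in which this site had a mutation change of 28.2 points. At Ψ93, in CUGCGAAUGGCUCAU (86 to 100), it was 0.406 points with HIV RT, -0.405 points with manganese and -0.154 points with magnesium, all small beside its mutation change of 15.6 points with HIV RT.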

How the results depend on the processing

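CMC and mock libraries were compared within each condition, and no fit of CMC across the 3 pairs was made. With 1 library per group none was left out. Of 186 recomputed values, 145 kept their direction and stayed within the main interval, within 1.5 times the main count or on the same side of a threshold, and none reversed. These 145 include log2 ratios, which are in another unit and can be compared with the main values by direction only. They also include values that could not move. Every listed site had at least 7069 crossing reads, so minimums of 30 and 1000 reads left the list values as they were. The listed sites stayed above all matched random lists in every alternative, including unlisted U far from listed sites as the background, an alternative chosen after seeing the data. Pooling reads moved the mutation change at listed sites to 6.48 points (HIV RT), 6.38 (manganese) and 1.46 (magnesium) and the stop change to 20.5, 17.3 and 26.6 points. An unweighted mean, added after seeing the data, gave 6.43, 5.57 and 1.26 points for mutation and 18.0, 13.4 and 21.5 for stops, so part of the move comes from taking a mean. Pooling gave an HIV RT minus manganese stop difference of 3.23 points whose interval included 0. Other differences kept their direction but moved in size when pooled, the mutation difference to 0.105 points (HIV RT minus manganese) and 4.91 (manganese minus magnesium) and the stop difference to -6.07 (HIV RT minus magnesium). Stops read 1 nt 5′ of the site gave 8.25 points with HIV RT and 4.44 with magnesium, and 1 nt 3′ gave 2.60, 1.78 and 2.24 points (HIV RT, manganese, magnesium). In 18S alone the stop change with magnesium was 22.5 points. Counts moved with the size bar by construction. For mutation, 2 points gave 295, 373 and 48 positions and 10 points gave 26, 17 and 7. For stops, 2 points gave 1501, 1129 and 1237 and 10 points gave 284, 258 and 323. The 99th percentile bar gave 58 mutation positions with manganese and 101, 86 and 103 stop positions. It is set on the unlisted positions themselves, so the stop totals are largely fixed by it. In the CMC libraries alone the HIV RT minus manganese mutation difference was 1.08 points and its interval excluded 0. Among called sites alone rho between mutation and stop was -0.319, -0.551 and -0.211 (HIV RT, manganese, magnesium), but dropping sites low in both measures pushes rho down by construction. The 3′ base range for magnesium mutation fell to the 90.5th percentile of shuffles among sites with no other within 3 nt. There the 5′ base range rose to percentiles 91.1 and 52.1 for stops (HIV RT, manganese) and 62.4 for magnesium mutation, still under 95. As means over sites the mismatches with HIV RT and CMC were 20.9% A, 67.6% C and 11.6% G, and the G share was 14.8% with manganese and 14.3% with magnesium. Where no cause is given, the cause was not tested. Coverage minimums of 30 and 1000 reads moved no call count by over 1.5 times, so depth limits few positions, while the single library per group limits every comparison.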

Other observations

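Of the tests in this part, those on reads booked 5′ of a site and on unlisted U between G were chosen before their results were seen, and the others after. Of the 8 usable pseudouridines listed as doubtful, Ψ1004, Ψ1045 and Ψ1177 of 18S were called for stop in all 3 conditions. Their stop changes were 5.41, 11.2 and 15.96 points at Ψ1004, 19.5, 44.3 and 37.4 at Ψ1045 and 9.12, 16.9 and 32.1 at Ψ1177 (HIV RT, manganese, magnesium). With HIV RT their mutation changes were 22.1, 9.45 and 22.8 points. Ψ1003 and Ψ1596 of 18S and Ψ4569 of 28S were not called in any condition, with HIV RT mutation changes of 1.21, -0.406 and 3.10 points and stop changes of 4.26, 1.04 and -0.448 points. Of the remaining doubtful sites, Ψ897 was called for stop with HIV RT alone and Ψ1243 for stop with HIV RT and manganese (10.8 and 6.00 points). Ψ1243 lies 1 nt 5′ of the listed Ψ1244, whose stop changes were 25.8, 25.0 and 26.4 points, and Ψ1045 lies 1 nt 5′ of the listed Ψ1046, with 13.2, 9.62 and 14.1 points. The median stop change 1 nt 5′ of listed sites with no other within 3 nt was 7.29, 5.79 and 4.11 points, so the calls at Ψ1243 are not evidence of a site of its own.

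Away from the listed sites (over 3 nt), 131 of 929 unlisted U were called for stop in all 3 conditions, and 5 of these were also called for mutation in at least 1. By mean stop change over conditions the leading positions were U 1792 of 28S (38.5 points), U 3595 of 28S (30.4), its neighbourhood being CGGCGCCUAGCAGCC (3588 to 3602), and U 1791 of 28S (27.4). In 18S it was U 1560 (24.2), in CCUACCCUACGCCGG (1553 to 1567). These positions were picked by their values and are not claimed as modified.

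Unlisted U as a class had more stops after CMC, with medians of 2.89, 1.17 and 3.49 points. RNA damage striking all bases alike would raise all of them, but the upper bounds at A, C and G were at most 0.0392 times the lower bound at U in every condition. Damage that favours certain bases or neighbouring bases was not tested, and this comparison cannot exclude it. Unlisted U before an A had median stop changes of 8.61, 7.54 and 10.9 points, against 1.53, 0.193 and 1.93 before a C. A minority of unlisted pseudouridines alone would leave the median U unchanged, yet the lower bound at U exceeded the upper bounds at the other bases by at least 0.986 points. CMC left on U and G could raise both. The mutation change at G lay above those at A and C in 2 of 3 conditions (0.183 points at G against -0.121 and -0.0991 with HIV RT), with magnesium the exception. The stop change at G lay above those at A and C with manganese (0.0103 points against -0.0566 and -0.0901) and magnesium (0.0953 against -0.254 and -0.235), but not with HIV RT (-0.0405 against -0.0218 and -0.0357). The 2 measures set different conditions apart, so this explanation stays open. A biological explanation was not tested.

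Mismatches at pseudouridines may come from copying past the CMC group or from bases that the enzyme adds without a template after stopping. Added bases would move the read start, so stops booked 2 to 4 nt 5′ of the site would be at least as many as the excess mismatched reads. The median ratio was 0.767 over the 41 sites called with HIV RT (interval 0.404 to 1.10) and 0.925 over the 37 called with manganese (0.555 to 1.43). The ratio was below 1 at 24 and 19 of these sites, and it counts all excess stops booked 2 to 4 nt 5′, whatever their origin. The 2 origins cannot be told apart with these tables, which hold no read-level link between a mismatch and a read start.

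The hypermodified U at 1248 of 18S gained stops after CMC with HIV RT and magnesium although CMC's usual site on pseudouridine, the N3, is taken there. If only molecules lacking the aminocarboxypropyl group reacted, the reads that pass would be enriched for the modified form and their mismatch share would rise. It was lower in all 3 conditions, with changes of -26.7, -9.26 and -7.41 points and Wilson intervals apart. The share also fell at some other controls, by 11.1 points at 4530 with HIV RT and 4.70 points at 1322 with magnesium. With manganese it rose by 1.42 points at 4530, 0.834 at 1850 and 1.92 at 1851, and at 1322 with HIV RT it changed by 0.171 points. At 1248 the stop gain was not called with manganese. With HIV RT the share changed by -1.06 points at 1850 and -0.0868 at 1851. With magnesium it changed by -0.659 points at 4530, -0.370 at 1850 and -0.0805 at 1851. A fall not specific to this site could therefore hide a rise with HIV RT and magnesium, so the lower mismatch share decides nothing there. The size of the stop gain does not depend on such a fall. Molecules without the group read as U in the mock library, where reads that pass as U were 16.9% of those reaching the site with HIV RT and 24.1% with magnesium. The stop gains were 40.6 and 41.4 points, above these shares by at least 16.4 points between the bounds. Reads that ended right after copying the site are not counted there, so these shares are not upper limits. Stops booked 1 nt 5′ of the site were 6.06% in the HIV RT mock library and 28.4% in the magnesium one. With magnesium the uncounted reads could close the gap, so no conclusion is drawn. With HIV RT a smaller share is left out. There the gap argues against molecules lacking the group as the whole cause if stopped and passing cDNAs are recovered alike. A reaction of the carbodiimide with the carboxyl group of the side chain is a candidate explanation that no test here addresses.

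The 3 listed pseudouridines with G on both sides, Ψ406, Ψ4471 and Ψ4521, were the 3 with a mutation call with magnesium, while none of the other 95 was called and their highest change was 3.98 points. This may be an effect of G on both sides. On other positions, unlisted U between 2 G (113) had a median mutation change with magnesium of 0.199 points (0.145 to 0.277) against 0.120 (0.113 to 0.130) at 931 other unlisted U, a difference of 0.0791 points in the direction this hypothesis needs. With HIV RT the medians were 1.89 and 0.791 points and with manganese 1.44 and 0.629. The other unlisted U mix all neighbouring bases. Unlisted U with a 3′ G, whatever the 5′ base, had 1.58 points with HIV RT, 0.972 with manganese and 0.119 with magnesium. With HIV RT and manganese the comparison therefore does not separate G on both sides from a 3′ G alone. The sizes at unlisted U are far below those at the 3 sites, and the hypothesis was formed on the same libraries.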
